A study of Danio rerio with 20 samples.

How the data were processed

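RNA sequencing was done on zebrafish larvae at 4 days after fertilization. The labels describe 10 libraries from larvae homozygous for the Q63X allele of mecp2, a nonsense allele, and 10 libraries from wild-type larvae. Each library was made from a pool of 3 whole embryos, and the labels call the pools biological replicates. Per the labels' protocols, the larvae came from incrosses of adults of one genotype, either homozygous mutant or wild type, so mutant and wild-type larvae had different parents. The labels name no clutch, day or sequencing batch, so none of these could be separated from genotype.

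Per the labels' protocols, libraries were made with a stranded poly-A mRNA kit. Per the submitters' processing notes, reads were processed with STAR 2.5.3a and RSEM 1.3.0 on the GRCz11 genome build. The annotation release and the authors' statistical test are not given in the sources used here. RSEM divides reads that fit several genes between them, so near-identical gene copies and overlapping genes share reads by estimate. The deposited values were read as RSEM expected counts per gene, an estimated number of reads that is not normalized for depth. Every value in the deposited table is a whole number, so no rounding was needed here. The table has 32520 genes, of which 51 have no symbol, and 1294 genes have a symbol that belongs to at least 1 other identifier as well.

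From these counts, library totals were summed over all genes. They ranged from 4893965 counted reads (mutant 7) to 15902577 (mutant 4), with a median of 12750406. Genes were kept for testing with edgeR 4.0.16's filterByExpr (minimum count 10, minimum total count 15, by genotype), which left 20580 genes. Libraries were scaled by the trimmed mean of M-values (TMM). Mutant and wild type were compared with edgeR's quasi-likelihood test with robust dispersions, no covariate, and Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. Fold changes are mutant over wild type, and standard errors are those of the fitted log2 fold change. Levels are CPM, the count per 1e+06 counted reads, on TMM-scaled library sizes, as mean ± SD over 10 libraries. A fold against a group with 0 reads in every library was computed against a floor of 3 reads over that group, which covers counting error only. Genes called "higher" or "lower" passed the adjusted threshold.

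Before the data were examined, 44 gene lists were written from textbook knowledge, covering partners of MeCP2, neural functions, stress and metabolic responses, and markers of the other tissues of a whole larva. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with a correlation estimated per list, and with fry, which asks whether the genes of a list move one way without comparing them with other genes. A score per library, the mean of the standardized log2 CPM of the members, was compared between the groups with a two-sided permutation test (1e+05 permutations of the library labels), a test added after seeing the data. All of these were adjusted over the 44 lists. Members were also counted when "adjusted over the list alone". The rule for named genes was fixed before the data were examined: mecp2; the 12 largest rises and 12 largest falls among called genes with a mean CPM of at least 1, a symbol that is not a placeholder and at least 9 of 10 mutant libraries on the side of the change; the 5 smallest p-values in each direction; up to 4 called members of each list; and up to 3 tested genes on either side of mecp2. Only part of the genes that this rule allows are named, to keep the text short. List members were named only where their call held with each library left out, a choice that rests on these same data. Genes named outside the fixed rule are marked as such.

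The gene table available for gene order is of the GRCz12tu assembly, which differs from that of the counts. It was used only for the order of genes and for which genes share a chromosome, matched by unique symbol or synonym (17402 of 20580 tested genes, 84.6%), and no coordinates are given. A planned comparison of fold change with gene length was not made, because gene lengths on the build of the counts were not used here.

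Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors inside edgeR (RLE), no low-count filter, a stricter filter (CPM of at least 1 in at least 10 libraries), the replicate number as a block, surrogate variables from sva 3.50.0 (6 variables), an estimated correlation for the lists, and leaving out each library in turn. Alternatives added after seeing the data summed the counts of identifiers with the same symbol, or left out the 4 libraries that stand apart from their group, by a median rank correlation with it more than 3 median absolute deviations low (wild type 3 and 10, mutant 3 and 7), or mutants 3, 6 and 9, which lie farthest from wild type on the first principal component. No pair of libraries in a group was as close as sampling noise: the lowest chi-square per degree of freedom was 6.05 among mutants and 6.21 among wild types.

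The gene test was tested on simulated data drawn from the means, library sizes and dispersions of the comparison of mutant with wild type. On 20471 simulated genes, edgeR called 34.7% of genes changed 1.25-fold, 78% of those changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold. Of its 173 calls, 7 were of unchanged genes. The 4 folds were given to 49, 50, 50 and 50 simulated genes, so a smaller share changed than the 9.74% called in the data. The adjusted threshold depends on that share, so the percentages recovered need not carry over to the data. To see what depth limits, the counts of every library were also thinned at random to 50% and 25% of its reads and tested again. In the simulation, with members drawn independently, camera passed a list of 50 genes raised 1.3-fold and 0 of 100 unchanged lists.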

Results

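Gene expression was measured by poly-A RNA sequencing in pools of 3 whole zebrafish larvae at 4 days after fertilization. There were 10 pools homozygous for the Q63X nonsense allele of mecp2 and 10 wild-type pools. MeCP2 binds methylated DNA, and loss of the human gene underlies Rett syndrome. Library totals in wild type ranged from 10746081 to 14928656 counted reads. In mutants they ranged from 4893965 (mutant 7) to 15902577 (mutant 4), and mutants other than mutant 7 had at least 11037313. Between 23144 and 24510 genes had at least 1 read per library.

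The mutated gene was lower in mutants. The transcript of mecp2 (ENSDARG00000014218) stood at 5.99 ± 0.943 CPM in wild type and 3.81 ± 0.828 CPM in mutants (SD, n = 10 each). The fitted log2 fold change was -0.67 (SE 0.12), with an edgeR adjusted p of 0.000662, and all 10 mutant libraries lay below the wild-type median. Wild-type libraries 1 to 10 read 6.19, 7.42, 4.57, 5.6, 5.66, 4.93, 6.17, 6.15, 5.64 and 7.52 CPM. Mutant libraries 1 to 10 read 2.67, 4.26, 3.96, 3.72, 5.12, 2.99, 4.75, 3.77, 4.18 and 2.69 CPM, so the groups overlapped. A nonsense allele does not remove the transcript, so its level does not by itself check each label.

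The comparison of mutant with wild-type larvae asks which transcripts change without functional MeCP2. Of 64 cell cycle genes 34 were lower in mutants, and 18 of 54 liver genes were. Of 42 genes of cholesterol and fatty acid synthesis 17 were higher, as were 19 of 42 of the endoplasmic reticulum stress response. These 4 lists passed camera with a preset correlation and did not with an estimated one (adjusted p = 0.303 for 3 of them and 0.366 for liver). Among single genes, the iron hormone hamp and the immune genes irg1l, mpeg1.2, ccl20a.3 and ccl20b rose, and dagla, which encodes a lipase that makes an endocannabinoid, fell from 91.6 ± 15.3 to 18 ± 2.8 CPM. Of 20580 genes tested, 1073 were higher and 932 lower in mutants, which is 9.74% of the genes, by edgeR's quasi-likelihood test. The changes were mostly small, with a median absolute log2 fold change of 0.41 among called genes. Of the called genes 98 were at least 2-fold higher and 92 at least 2-fold lower. For 140 genes no mutant library overlapped a wild-type library, which chance gives for 0.00108% of splits. The first principal component, with 20.4% of the variance, separated the genotypes. With surrogate variables in the model 711 genes were higher and 857 lower, without the 4 libraries that stand apart 817 and 869, and without mutants 3, 6 and 9 700 and 576, so that higher genes were the larger number in some fits and lower genes in others.

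**Figure D1:**
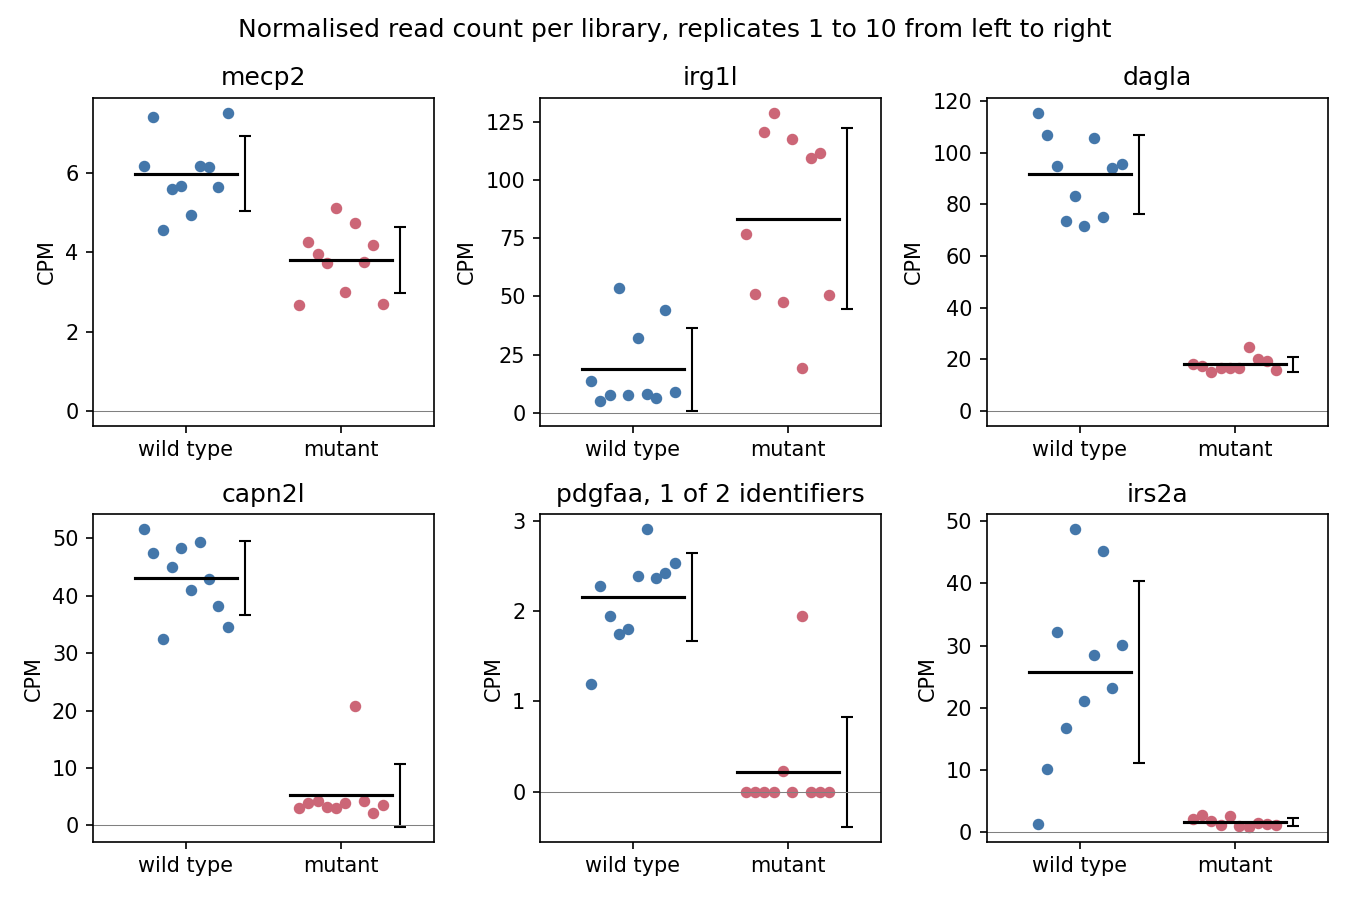
Normalised read count (CPM) of 6 genes in each library, wild type in blue and mutant in red, with replicates 1 to 10 from left to right. Horizontal lines are means and bars are SD (n = 10); capn2l stands at 20.7 CPM and 1 of the 2 pdgfaa identifiers at 1.94 CPM in mutant 7, and irs2a at 1.43 CPM in wild type 1, apart from the rest of their groups.

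Several of the largest rises were immune genes. Hepcidin, encoded by hamp, restrains iron export and is induced in inflammation; it rose from 0.594 ± 1.12 to 8 ± 3.47 CPM (log2 fold change 3.67, SE 0.53, edgeR adjusted p = 0.000164), with no overlap between the groups, and the log2 fold change was 5.00 without wild type 5, which had 3.66 CPM. The transcript of irg1l, whose product makes itaconate, rose from 18.7 ± 17.8 to 83.4 ± 39 CPM (2.17, SE 0.47, edgeR adjusted p = 0.00576). Wild-type libraries 4, 6 and 9 had 53.6, 32.2 and 43.9 CPM of irg1l, above mutant 7 with 19.4 CPM. The macrophage perforin mpeg1.2 rose from 29.6 ± 15.2 to 90.7 ± 25 CPM (1.62, SE 0.25). The chemokines ccl20a.3 and ccl20b rose by 2.21 (SE 0.31) and 1.94 (SE 0.22) on the log2 scale, and the chemokine receptor ccr11.1 and ms4a17a.8 by 1.57 and 2.51. All 10 mutant libraries lay above the wild-type median for each of these genes. The complement gene c6 has 2 identifiers, and only the scarcer one rose, by 1.71 (SE 0.39), from 0.778 ± 0.486 to 2.55 ± 1.84 CPM. The other c6 identifier stood at 26.9 ± 6.48 CPM in wild type and 26.4 ± 19.1 CPM in mutants, and with both summed the log2 fold change was 0.07 (edgeR adjusted p = 0.919). The call of c6 was also lost with surrogate variables (edgeR adjusted p = 0.0839).

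Other large rises were in genes of varied function. The ubiquitin ligase gene rnf150b rose to 40.1 ± 7.64 CPM (3.61-fold; log2 fold change 1.85, SE 0.10, edgeR adjusted p = 1.27e-13), and the receptor kinase gene grk5 from 5.3 ± 0.805 to 11.8 ± 1.12 CPM (1.15, SE 0.09). The gene sh3d21 rose by 0.60 (SE 0.06). Transcripts of fgfr1bl were not detected in any wild-type library (0 reads) and stood at 2.81 ± 1.11 CPM in mutants, at least 117-fold higher against a floor of 3 reads over the wild-type group. A second identifier of fgfr1bl, which did not pass the low-count filter, also had 0 reads in wild type and 260 in mutants. The zinc finger gene znf1179 rose from 37.1 ± 29 to 110 ± 18.8 CPM (1.56, SE 0.47, edgeR adjusted p = 0.0427). In wild type, znf1179 stood at 3.29, 3.04 and 2.56 CPM in libraries 2, 5 and 8 and at 32.6 to 82.5 CPM in the others. It missed the threshold in 14 of the 20 fits that left out 1 library, with adjusted p up to 0.0682; these were wild types 1, 4, 6, 9 and 10 and mutants 2 to 10. The mitochondrial transcript mt-atp8, whose gene overlaps mt-atp6, rose by 3.03 (SE 0.78) through a few libraries: mutants 6, 8, 9 and 10 had 23.4, 64.6, 7.96 and 64.1 CPM, and the other 6 mutants had 2.12 to 3.45 CPM, beside 1.26 to 5 CPM in wild type. The call of mt-atp8 was lost with limma-voom (adjusted p = 0.222) and with surrogate variables (edgeR adjusted p = 0.0605), and that of znf1179 with surrogate variables (0.133), with no low-count filter (0.0515), without the 4 libraries that stand apart (0.0702) and without mutants 3, 6 and 9 (0.102).

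The largest falls included signalling and metabolic genes. Transcripts of dagla fell by 2.36 on the log2 scale (SE 0.09, edgeR adjusted p = 5.36e-16). Of the 2 identifiers of the growth factor gene pdgfaa, 1 (ENSDARG00000109371) fell from 2.16 ± 0.491 to 0.217 ± 0.61 CPM (-4.32, SE 0.55), with 0 reads in 8 mutant libraries and 1.94 CPM in mutant 7, without which the log2 fold change was -5.99. The other rose from 5.86 ± 1.2 to 8.9 ± 1.88 CPM (0.61, SE 0.12), and with both summed pdgfaa stood at 8.02 ± 1.3 and 9.12 ± 1.64 CPM (log2 fold change 0.18, SE 0.11, edgeR adjusted p = 0.295). The calpain gene capn2l fell from 43.1 ± 6.44 to 5.2 ± 5.49 CPM (-3.29, SE 0.28), and mutant 7 stood at 20.7 CPM against 2.13 to 4.32 CPM in the other 9. The insulin receptor substrate gene irs2a fell from 25.7 ± 14.6 to 1.66 ± 0.655 CPM (-3.90, SE 0.45), with wild type 1 at 1.43 CPM. Further falls were of cyp2x12 (-2.49), the chitinase gene chia.3 (-2.10), hpxa (-2.07), the complement factor H-like gene cfhl2 (-2.06), the fructose transporter gene slc2a5 (-2.04), cst14a.1 (-1.93), the elastase gene cela1.3 (-1.79) and cyp2aa4 (-1.76). For cfhl2, wild types 4, 7 and 10 stood at 0.606, 0.496 and 0.447 CPM, within the mutant range of 0.301 to 1.08 CPM. The other wild types had 3.58 to 6.52 CPM of cfhl2. The calls of hpxa and cela1.3 were lost without mutants 3, 6 and 9 (edgeR adjusted p = 0.0654 and 0.0911), that of hpxa with surrogate variables (edgeR adjusted p = 0.0837), and those of cela1.3 and cfhl2 with limma-voom (adjusted p = 0.0732 and 0.115). Beside dagla, the named falls with the smallest adjusted p were those of yipf3 (-0.57, SE 0.05), tp53bp2a (-1.53, SE 0.12), the semaphorin receptor gene plxnb2b (-1.26, SE 0.11) and the chemokine gene cxcl12b (-0.75, SE 0.07).

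**Figure D2:**
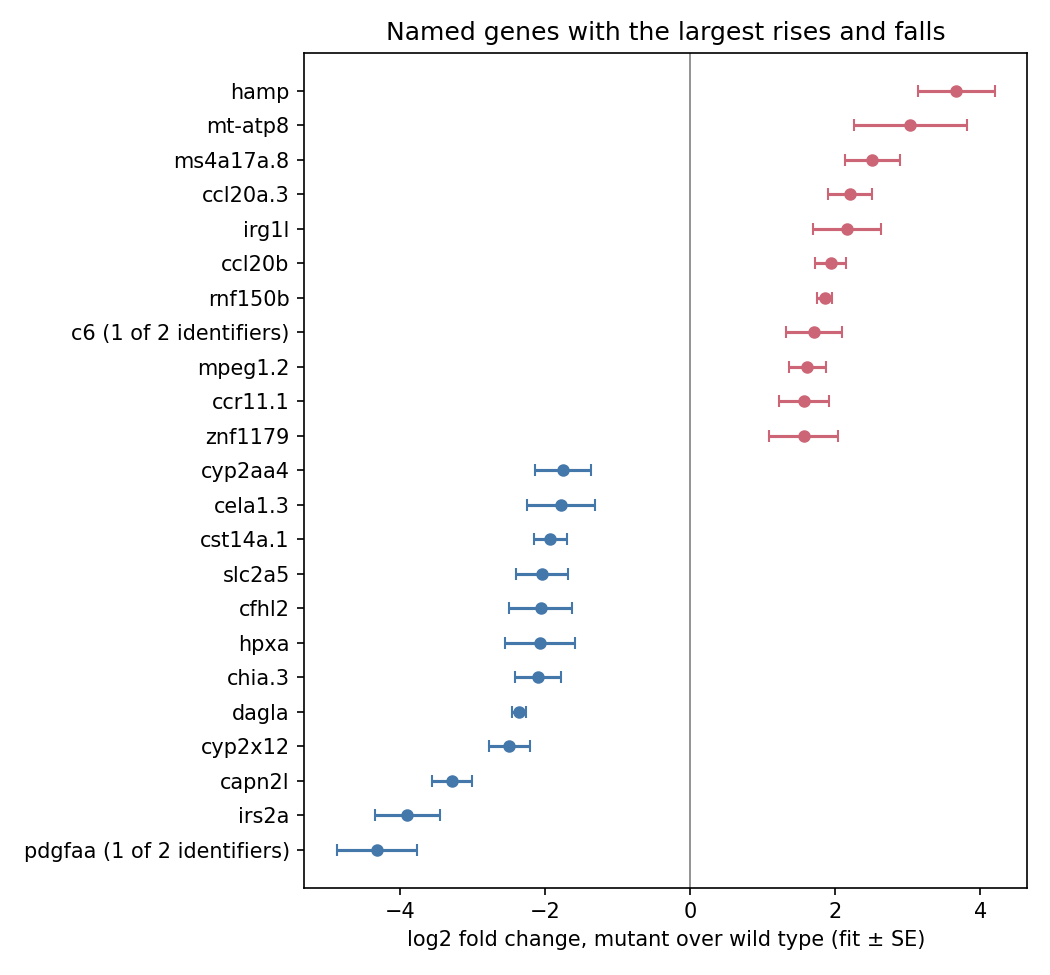
Fitted log2 fold change, mutant over wild type, of 23 of the 24 named genes with the largest rises and falls (x axis); bars are SE (n = 10 per group). The gene fgfr1bl is left out because its wild-type libraries had 0 reads; hamp rose by 3.67 and 1 of the 2 pdgfaa identifiers fell by 4.32.

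Genes of the cell cycle fell together. Of 64 measured members, 34 were lower and 0 higher, and 42 were lower and 1 higher when adjusted over the list alone, with a median log2 fold change of -0.29. The mitotic genes cdc25b (-0.48, SE 0.06), espl1 (separase, -0.66, SE 0.09), kif11 (-0.47, SE 0.07) and ccna2 (cyclin A2, -0.46, SE 0.07) were lower in all 10 mutant libraries than the wild-type median. The list passed camera with a preset correlation (adjusted p = 3.49e-16) and did not with an estimated correlation (adjusted p = 0.303). Its score per library was lower in mutants (permutation test, adjusted p = 0.00557), with 10 of 10 mutants below the wild-type median. Without the 4 libraries that stand apart 34 members were lower, and without mutants 3, 6 and 9 28 were.

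Genes of cholesterol and fatty acid synthesis rose, with 17 of 42 members higher and 0 lower (22 and 0 adjusted over the list alone). They included hmgcs1 (0.79, SE 0.10), the lanosterol demethylase gene cyp51 (0.91, SE 0.13), fdps (0.50, SE 0.09) and pmvk (0.66, SE 0.12), all enzymes of the sterol pathway. In the endoplasmic reticulum stress list 19 of 42 members were higher and 1 lower (19 and 1 adjusted over the list alone), among them the chaperone and folding genes manf (0.56, SE 0.08), pdia4 (0.44, SE 0.07), hyou1 (0.52, SE 0.09) and hsp90b1 (0.36, SE 0.07). The camera adjusted p was 1.87e-09 for the first list and 1.49e-06 for the second, and 0.303 for both with an estimated correlation. Both scores were higher in mutants (permutation test, adjusted p = 0.00557 for each), in 10 of 10 mutants relative to the wild-type median.

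Liver genes fell, with 18 of 54 members lower and 0 higher (28 lower and 1 higher adjusted over the list alone) and a median of -0.28. Transferrin (tfa) fell from 1514 ± 215 to 855 ± 237 CPM (-0.82, SE 0.13), and ces3 (-0.67, SE 0.11), the apolipoprotein B gene apoba (-0.45, SE 0.09) and ambp (-0.37, SE 0.07) fell as well. The camera adjusted p was 5.62e-10 (0.366 with an estimated correlation), and the score was lower in 10 of 10 mutants (permutation test, adjusted p = 0.0151). The complement genes c8g (-0.48, SE 0.09) and c3a.2 (-0.58, SE 0.12), which the liver secretes, were also lower. In the glycolysis and gluconeogenesis list 4 of 54 members were higher, among them the hexokinase gene hk2 (0.80, SE 0.15), and 5 were lower (4 and 10 adjusted over the list alone). In the exocrine pancreas list 1 of 33 was higher and 4 lower (1 and 6 adjusted over the list alone), and in the intestine list 1 of 46 was higher and 5 lower (4 and 7 adjusted over the list alone).

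**Figure D3:**
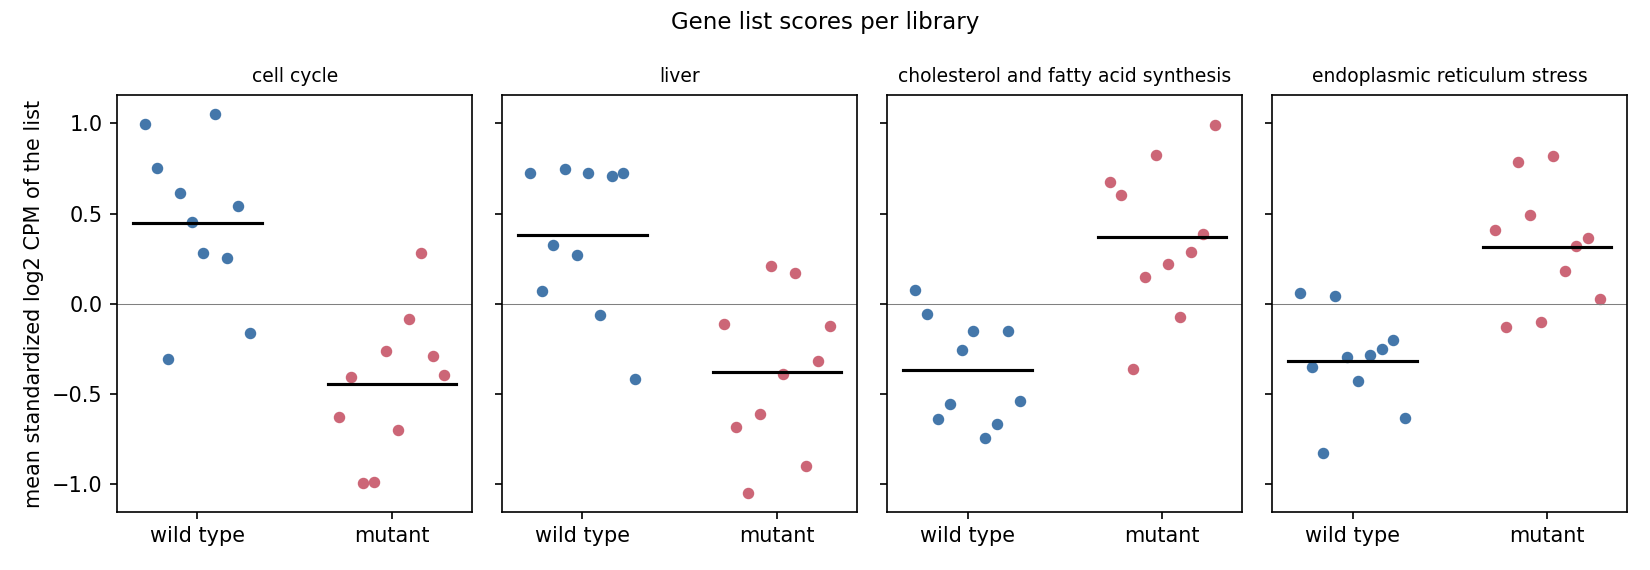
Score of 4 gene lists in each library, the mean standardized log2 CPM of the members (y axis), with wild type in blue, mutants in red and lines at group means (n = 10 each). The cell cycle and liver scores were lower in mutants and the other 2 higher, with permutation adjusted p of 0.00557, 0.0151, 0.00557 and 0.00557.

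Some stress and hormone genes rose. Of the 29 immediate-early genes measured 5 were higher and 0 lower (7 and 0 adjusted over the list alone), among them junbb (0.82, SE 0.13) and atf3 (0.82, SE 0.16). The list passed camera (adjusted p = 0.00371; 0.5 with an estimated correlation), and its score did not pass after adjustment (permutation adjusted p = 0.0615, 9 of 10 mutants above the wild-type median). Of 32 neuropeptide and pituitary hormone genes 4 were higher and 0 lower (8 and 0 adjusted over the list alone), with penkb, a proenkephalin gene, from 5.4 ± 0.855 to 7.51 ± 0.595 CPM without overlap. That list passed camera (adjusted p = 0.000934; 0.5 with an estimated correlation) and the score test (permutation adjusted p = 0.0365, 9 of 10 mutants). Of 26 p53 targets 2 were higher and 0 lower (3 and 0 adjusted over the list alone), including casp8 (0.35, SE 0.09). The list passed camera (adjusted p = 0.0097; 0.5 with an estimated correlation) and the score test (permutation adjusted p = 0.0166, 10 of 10 mutants), and its camera call was lost with surrogate variables (0.298) and without mutants 3, 6 and 9 (0.118), as was the edgeR call of casp8 (0.1 and 0.125). In the glucocorticoid and stress axis 4 of 26 genes were higher and 0 lower (5 and 1 adjusted over the list alone), including the steroid synthesis genes cyp17a1 (0.61, SE 0.12) and star (0.52, SE 0.12) and the receptor gene crhr1 (0.42, SE 0.12), and the list did not pass camera (adjusted p = 0.151). The edgeR call of crhr1 was lost without the 4 libraries that stand apart (adjusted p = 0.0648).

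Several lists had members on both sides. Of 35 macrophage, microglia and neutrophil genes 3 were higher and 6 lower (6 and 9 adjusted over the list alone): mpeg1.2 rose, whereas the receptor gene csf1ra (-0.79, SE 0.11), the neutrophil peroxidase gene mpx (-0.49, SE 0.12) and the leukocyte gene lcp1 (-0.37, SE 0.09) fell. The call of lcp1 was lost without mutants 3, 6 and 9 (edgeR adjusted p = 0.0768). Of 42 inflammation and complement genes 8 were higher and 6 lower (14 and 11 adjusted over the list alone). Of 19 interferon response genes 3 were higher and 1, b2m (-0.64, SE 0.17), was lower (5 and 1 adjusted over the list alone). Of 16 antigen presentation genes 0 were higher and 2, b2m and cd74b (-1.09, SE 0.27), were lower (1 and 4 adjusted over the list alone). Among 37 heat shock and chaperone genes 4 were higher, including hspa4a (0.46, SE 0.10), and 4 lower, including the neighbouring genes hsp70.2 (-1.31, SE 0.31) and hsp70.3 (-1.73, SE 0.38; 5 and 4 adjusted over the list alone). Of 49 oxidative stress genes 8 were higher, including the ferritin heavy chain copies fthl28 (0.89, SE 0.14) and fthl30 (0.87, SE 0.14), and 6 lower, including the autophagy receptor gene sqstm1 (-0.45, SE 0.08; 9 and 6 adjusted over the list alone). Of 41 skin and keratin genes 4 were higher, including cldne (0.41, SE 0.06), and 12 lower, including krt17 (-0.80, SE 0.12), krt94 (-0.30, SE 0.05) and epcam (-0.44, SE 0.08). The ionocyte list had 4 of 26 members higher and 0 lower, among them the ammonia transporter gene rhcga (1.17, SE 0.17), the calcium channel gene trpv6 (0.57, SE 0.10), ca15a (0.39, SE 0.08) and ca2 (0.30, SE 0.07). The call of ca2 was lost with surrogate variables (edgeR adjusted p = 0.111).

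Some genes of the neural lists were called, beside 9.74% of all tested genes. The synaptic transmission, neuron marker, hair cell and phototransduction lists lay below that share. The radial glia, oligodendrocyte, monoamine and opioid lists lay above it. Of 72 synaptic transmission genes 1 was higher and 3 lower, of 32 neuron markers 2 were lower, of 26 radial glia and astroglia genes 1 was higher and 2 lower, and of 27 oligodendrocyte and myelin genes 4 were higher and 2 lower. Of 23 monoamine genes 3 were higher, of 21 opioid and pain genes 4 (5 adjusted over the list alone), and of 33 hair cell and otic genes 1, with 0 lower in each. Among 55 phototransduction genes 3 were lower and 0 higher. Of 37 MeCP2 partners and DNA methylation genes, mecp2 itself and zbtb4 (-0.32, SE 0.07) were lower and the corepressor gene tbl1x (0.44, SE 0.08) was higher. Of 38 circadian clock genes 2 were higher and 2 lower.

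In the remaining tissue and metabolic lists the counts of higher and lower members were 0 and 4 of 49 for fast muscle, where casq1a fell by 0.42 (SE 0.09), 0 and 1 of 16 for slow muscle, and 1 and 2 of 26 for cardiac muscle. They were 0 and 1 of 46 for lens crystallins, 0 and 2 of 23 for haemoglobin and erythroid genes, 1 and 4 of 28 for pigment cells, 1 and 1 of 36 for cartilage and bone, 1 and 2 of 55 for extracellular matrix, 3 and 0 of 36 for vascular genes, and 1 and 0 of 5 for hatching gland genes. They were 5 and 5 of 101 for nuclear-encoded oxidative phosphorylation, 1 and 0 of 13 for mitochondrially encoded genes, 1 and 2 of 83 for ribosomal proteins, and 2 and 1 of 29 for hypoxia genes. Of 16 endocrine pancreas genes 0 passed edgeR's test, with 0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom. Adjusted over the list alone, the counts of higher and lower members became 0 and 1 for neuron markers, 5 and 4 for oligodendrocytes, 0 and 2 for fast muscle, 0 and 0 for slow muscle, lens and cartilage, 2 and 7 for erythroid genes, 2 and 4 for pigment cells, 0 and 2 for ribosomal proteins and 2 and 2 for hypoxia. They were the same for the skin, ionocyte, synaptic, radial glia, monoamine, hair cell, phototransduction, MeCP2 partner, clock, cardiac, endocrine pancreas, matrix, vascular, hatching gland, oxidative phosphorylation and mitochondrially encoded lists. In all, 15 of the 44 lists passed camera with the preset correlation (6 higher, 9 lower), 0 passed with an estimated correlation (4 at an unadjusted p under 0.05), 7 passed fry and 6 passed the score test. Median and mean log2 fold change had opposite signs for macrophage, microglia and neutrophil genes (-0.02 and 0.000336), hair cells (-0.02 and 0.03), vascular genes (-0.03 and 0.02) and heat shock genes (0.04 and -0.05), and 0 of these 4 lists passed camera. Beside the lists named with a camera p above, those that passed were phototransduction, synaptic transmission, neuron markers, fast muscle, exocrine pancreas, lens, glycolysis and ionocytes, each with a permutation adjusted p of 0.126 or more on its score and 0.711 with an estimated correlation. Of these 8 lists, all but fast muscle lost the camera call without mutants 3, 6 and 9 (adjusted p = 0.0908 for phototransduction, 0.38 for synaptic transmission, 0.118 for exocrine pancreas and lens, and 0.113 for neuron markers, glycolysis and ionocytes). With surrogate variables phototransduction (0.186), synaptic transmission (0.0839, reversed), neuron markers (0.835), glycolysis (0.248) and ionocytes (0.738) lost it, without the 4 libraries that stand apart synaptic transmission (0.746), neuron markers (0.13) and ionocytes (0.214), and with limma-voom synaptic transmission and ionocytes (0.0511 each).

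**Figure D4:**
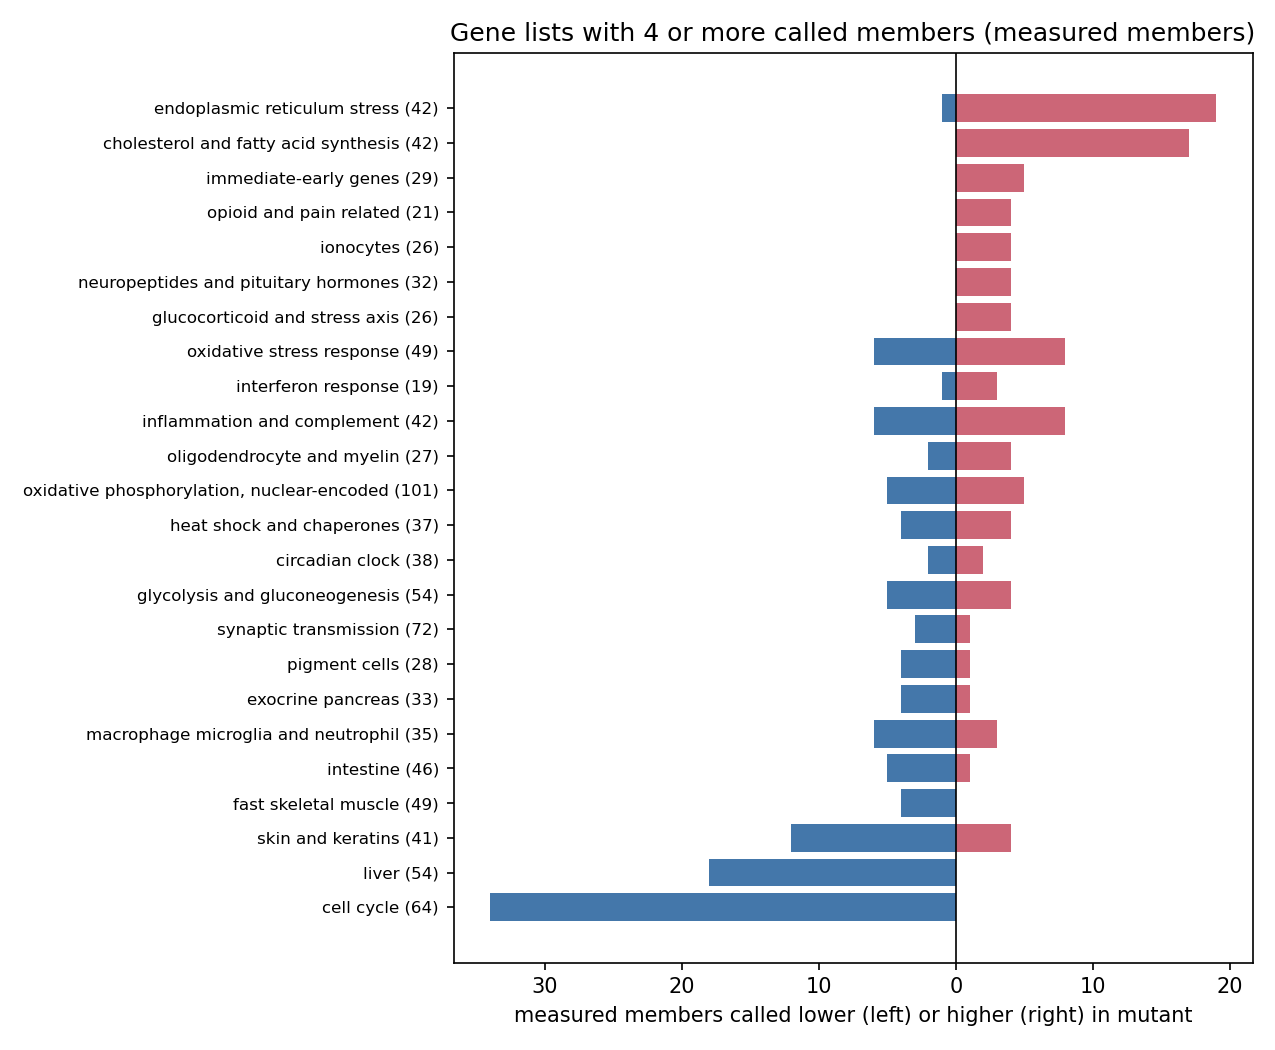
Number of measured members called lower (left, blue) or higher (right, red) in mutants by edgeR for each fixed list with 4 or more called members; the number in brackets is the number of measured members. Cell cycle had 34 lower, liver 18 lower, endoplasmic reticulum stress 19 higher and 1 lower, and cholesterol and fatty acid synthesis 17 higher.

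Mutant and wild-type larvae had different parents, so the chromosome region around mecp2 was also compared. Genes near mecp2 were called more often than genes elsewhere. Of the 100 tested genes nearest to mecp2 in gene order, 24 were called, against 9.81% of the other placed genes (Fisher's exact test, two-sided, odds ratio 2.9, p = 3.17e-05). Among the nearest 50 it was 13, and among the nearest 200 it was 36 (p = 0.000898 and 0.000458). Fisher's test takes genes as independent, whereas called genes lay together in gene order, so these p-values may be too small. Of windows of 100 genes along the chromosomes, 0.369% held as many called genes as the one around mecp2. Over the whole chromosome 91 of 768 tested genes were called, with an odds ratio of 1.24 (p = 0.0728, adjusted p = 0.303 over 25 chromosomes). The immediate tested neighbours cdk20, hcfc1b and irak1 on one side and fgd1, tfe3a and zgc:113363 on the other had log2 fold changes of -0.24, 0.24, -0.12, 0.08, -0.05 and -0.52. Of these hcfc1b passed edgeR's test (adjusted p = 0.0414), and it missed the threshold in 12 of the 20 fits that left out 1 library, with adjusted p up to 0.09, and without mutants 3, 6 and 9 (0.25) and with surrogate variables (0.065); these single libraries were wild types 1, 2, 4, 5, 7, 8 and 9 and mutants 3, 4, 5, 6 and 9. The gene zgc:113363 (edgeR adjusted p = 0.0588) passed without wild type 2 or 3 or mutant 2 or 7, down to an edgeR adjusted p of 0.0432, and with DESeq2 (adjusted p = 0.0449).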

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

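The comparisons with other splits of the libraries, camera on the lists, the share of direct neighbours among genes changed 2-fold and the share of those genes on the mecp2 chromosome were tests set before their results were seen, and the other tests in this part were chosen only after the result was seen. Of 260 groups of 10 values, 22 had 1 library far from the other 9, and chance gives about 1 in 20. These were 14 genes, 7 list scores and the library totals. A group in which several libraries lie apart together can go unflagged.

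Mutant 7 was low in total reads, with 4893965 (4.894 when counted in units of 1e+06) against 11037313 to 15902577 in the other mutants. It was low in irg1l (19.4 CPM, the others at least 47.4) and ccl20b (1.08 CPM, the others at least 2.88), and high in capn2l (20.7 CPM, the others at most 4.32), in the pdgfaa identifier that fell (1.94 CPM, the others at most 0.226) and in cxcl12b (24.8 CPM, the others at most 20.3). Mutant 1 was high in hpxa (14.1 CPM, the others at most 5.4), mutant 3 low in ccr11.1 (0.63 CPM, the others at least 1.14), and mutant 5 low in casq1a (90.6 CPM, the others at least 132). Wild type 1 was low in irs2a (1.43 CPM, the others at least 10.1), wild type 3 in casp8 (8.76 CPM, the others at least 10.9) and wild type 4 in fgd1 (6.13 CPM, the others at least 7.94). Wild type 10 was low in slc2a5 (0.298 CPM, the others at least 1.42), c8g (13.5 CPM, the others at least 17.9) and epcam (239 CPM, the others at least 302).

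Among list scores, wild type 10 was low for skin and keratins (-0.93), the oxidative stress response (-1.25) and cytosolic ribosomal proteins (-2.22). Wild type 7 was low for p53 targets (-0.95) and wild type 4 for hair cells (-0.73). Mutant 6 was high for inflammation and complement (0.80), and mutant 3 low for the exocrine pancreas (-1.81).

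A random division of the libraries as the source of the number of called genes is argued against by other splits. The real split of the libraries called 2005, and the highest of the other 99 splits drawn called 1. So 1 of 100 splits, the real one, gave as many. The splits treat the pools as independent. Each genotype had its own parents and no label names a clutch, so they cannot tell genotype from parents or clutch. A split that mixes the genotypes also holds their difference within its groups, which lowers its calls. Chance was not excluded for the number of lists that passed camera with the preset correlation. The real split passed 15 lists, the highest other split passed 22, and 31 of 100 splits passed as many as the real one.

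Genes changed 2-fold or more lay next to one another in gene order: of the 116 such genes with a place, 21.6% had another as direct neighbour, against 1.33% in shuffled orders (p = 1e-04, the smallest that 10000 shuffles can give), and 15 of 15 neighbouring pairs moved the same way. Some of these pairs share a gene, so they are not independent. Among all called genes 149 of 245 neighbouring pairs moved the same way. Called genes changed less than 2-fold also lay together, at 22% against 17.6% in shuffled orders (p = 4e-04 from the shuffles). For the placed genes, a haplotype carried along on the mecp2 chromosome as the main source is argued against by the 5.17% of genes changed 2-fold or more that lie there (95% interval 1.92% to 10.9%). Of the 190 genes changed 2-fold or more only 116 had a place, a smaller share than the 84.6% of all tested genes. The unplaced genes are not covered, and the interval takes the genes as independent. The region around mecp2 may still add to the pattern, since 3 of the 100 genes nearest to mecp2 were changed 2-fold (Fisher's exact test, two-sided, odds ratio 4.7, p = 0.0293). That test takes genes as independent, whereas these genes lay together in gene order, so its p may be too small. Wild-type RNA in mutant 7 is argued against by the 0% of the way to wild type (median, range -24.4% to 32.8%) that 18 other genes lower by 4-fold or more had moved there, against 43.6% for capn2l and 90.1% for the pdgfaa identifier. Like-named tandem copies as the whole cause of called genes of any size near genes changed 2-fold are argued against by the 12.3% called within 25 places with placeholder names and like-named pairs left out (9.65% in shuffled orders, upper bound of the middle 95% of orders 10.7%). Copies with unlike names pass that filter. The 12.2% called at 6 to 25 places with none left out (upper bound 10.8%) cannot decide this, because long tandem arrays reach those places. For the direct neighbours changed 2-fold, tandem gene copies cannot be told apart from haplotypes, since 10 of the 15 pairs hold a placeholder name, 4 are like-named, and with both kinds left out 2.56% of 78 genes had such a neighbour (upper bound of the middle 95% of shuffled orders 5.13%), nor can loss of mecp2 for capn2l, irs2a and pdgfaa, since each of these 3 genes had only 1 library nearer to the other group. Only these 3 genes were checked in that way, and wild types 4, 7 and 10 lay within the mutant range for cfhl2. The log2 fold change of 0.18 for pdgfaa with its identifiers summed fits a different division of reads between its identifiers, and the 24% of genes called among the 100 nearest to mecp2, a share that 0.369% of windows of that size reach, fits a haplotype linked to the mutation there. A candidate explanation for part of these changes is that the parents of mutant and wild-type larvae carried different haplotypes, and an effect of the mecp2 genotype on the other genes stays open, because the design gives each genotype its own parents.

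The fall of cell cycle genes is argued not to come from the 4 libraries that stand apart, since 34 members were lower without them, nor from scaling by library composition, which moves every gene alike, since the list's median lay 0.29 below that of all tested genes (difference -0.288, 95% interval over members -0.377 to -0.167). That interval treats the members as independent, whereas their estimated correlation was 0.274. It does not measure the spread between libraries. An older developmental age of the mutant larvae cannot be told apart from genotype, because the larvae had different parents. An older age would raise the 4 lists that rise with age (myelin, intestine, exocrine pancreas and phototransduction). All 4 scored lower in mutants, the opposite direction, but not beyond the spread of the libraries (smallest permutation p of 0.0972), so they do not decide it. A slower division of cells in mutants may be a biological reason, and it was not tested.

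The rise of mpeg1.2, irg1l, hamp and the ccl20 genes is argued not to come from more of both macrophages and neutrophils, since the 34 other markers of these cells had a median log2 fold change of -0.0254 (95% interval over markers, taken as independent, -0.28 to 0.07), with 2 higher and 6 lower. The markers pool both kinds of cell, so their median cannot exclude a rise of macrophages alone beside a fall of neutrophils. The rise of these genes is also argued not to come from mutants 3, 6 and 9 alone, since mpeg1.2, irg1l, hamp, ccl20a.3 and ccl20b passed without them, at edgeR adjusted p of 0.0404 or less. Rearing conditions or clutch cannot be told apart from genotype: 3 wild-type libraries had more irg1l than mutant 7, and no label names a clutch, tank or day. Mutant 7 also lay below wild type 4 for mpeg1.2 (47.5 against 54.4 CPM) and ccl20a.3 (1.73 against 2.73 CPM). For ccl20b it lay below wild type 6 (1.08 against 1.74 CPM), and for hamp the groups did not overlap. An inflammatory state of the mutant larvae is a possible explanation for these genes and stays open: the inflammation and complement list had 8 of 42 members higher and 6 lower and did not pass camera (adjusted p = 0.409), nor did the interferon response list (0.294).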

How the results depend on the processing

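The fits without the 4 libraries that stand apart, without mutants 3, 6 and 9, and with identifiers of the same symbol summed, the permutation of list scores and the draws of fewer reads were tests chosen only after the result was seen. Counts of higher and lower genes were 1349 and 1072 with DESeq2 (2004 of the 2005 calls shared), 1011 and 916 with limma-voom (1841), 1122 and 894 with RLE (1967), 1102 and 883 with no low-count filter (1817), 1061 and 914 with the stricter filter (1969), 1058 and 924 with identifiers summed (1955), 711 and 857 with surrogate variables (1175), 817 and 869 without the 4 libraries that stand apart (1380) and 700 and 576 without mutants 3, 6 and 9 (1102). They ranged from 826 to 1133 and from 739 to 986 when 1 library was left out. The replicate numbers did not pair the libraries: correlations of same-number pairs ran from -0.0872 to 0.0427 and 1 of 20 libraries correlated best with its own number. With the replicate block 841 and 735 genes were called (1500 shared), 17 lists passed camera, and 7 of 85 named genes lost their call. Lists passing camera numbered 0 with an estimated correlation, 8 without mutants 3, 6 and 9, 6 by permutation of scores, 13 to 18 in the other fits and 13 to 17 with 1 library left out. The fall of mecp2 passed in every fit, from -0.59 with surrogate variables to -0.73 with 1 library left out. The list members among the 85 named genes were chosen because their call held with each library left out, so those fits do not test their stability. Of 85 named genes, pdgfaa alone reversed in any of these fits, at 0.18 with identifiers summed. Its identifiers moved in opposite directions, and their sum fits a different division of reads between them. What would cause such a division was not tested.

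The odds ratio of called genes on the mecp2 chromosome was 1.3 with limma-voom (p = 0.0273) and 1.26 with RLE (p = 0.0484), and 1.16 to 1.37 with 1 library left out, where it passed without wild type 2, 3 or 6 or mutant 1, 2, 4, 6, 8 or 9. The direction of the following lists reversed, with these camera adjusted p. With surrogate variables they were cartilage and bone 0.357, circadian clock 0.393, endocrine pancreas 0.938, fibrillar collagen and extracellular matrix 0.0598, heat shock and chaperones 0.328, inflammation and complement 0.319, oligodendrocyte and myelin 0.53, oxidative phosphorylation, nuclear-encoded 0.0166, oxidative stress response 0.738, radial glia and astroglia 0.945 and synaptic transmission 0.0839. Without the 4 libraries that stand apart they were cartilage 0.722, clock 0.674, endocrine pancreas 0.797, matrix 0.797, heat shock 0.667 and oxidative phosphorylation 0.00102. Without mutants 3, 6 and 9 they were cartilage 0.958, clock 0.958, matrix 0.241, heat shock 0.249, inflammation 0.958, intestine 0.858 and oligodendrocytes 0.785. With 1 library left out the ranges were 0.461 to 0.997 for endocrine pancreas, 0.264 to 0.986 for matrix, 0.452 to 0.984 for heat shock, 0.515 to 0.986 for oligodendrocytes and 0.225 to 0.84 for oxidative phosphorylation. Among lists that passed, ionocytes missed the threshold without wild type 1, 3, 6, 7 or 10 or mutant 6 or 7 (up to 0.128), synaptic transmission without wild type 4, 6, 9 or 10 or mutant 3, 4, 6 or 7 (up to 0.247) and glycolysis without wild type 4 (0.0679). Among the others, cytosolic ribosomal proteins passed without wild type 6 or 10 or mutant 1, 3, 4 or 7 (down to 1.72e-06), haemoglobin and erythroid genes without wild type 3, 5 or 10 or mutant 3 or 10 (down to 0.0136), the intestine list without wild type 7 or mutant 1, 5, 7 or 10 (down to 0.0235) and skin and keratins without wild type 10 or mutant 7 (down to 0.00964). With surrogate variables 5 lists gained the camera call without reversing, among them the ribosomal, erythroid and skin lists (1.76e-10, 0.000266 and 0.000768). Lists also gained it without the 4 libraries that stand apart (5), with no low-count filter (3) and with the replicate block (2). With identifiers summed and without mutants 3, 6 and 9 it was 1 list each. The cause of these changes between fits was not tested. A planned comparison of fold change with gene length was not run. Depth limits the number of calls: with 50% of the reads of each library drawn at random 798 and 667 genes were called (1333 shared), and with 25% 524 and 401 (835). With 50% of the reads 67.9% of the calls of 2-fold changes and 66.3% of the smaller ones were shared.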

Other observations

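All tests in this part were chosen only after the result was seen. Of the called genes 432 have placeholder names, 225 higher and 207 lower in mutants, and no function is given for them. The following genes were chosen after their values were seen. Besides fgfr1bl, zgc:171490, si:dkey-19a16.7, CR352226.5 and zgc:171497 had 0 reads in every wild-type library and were at least 117-fold, 249-fold, 324-fold and 93.8-fold higher in mutants against a floor of 3 reads over the wild-type group. The genes si:dkeyp-51b9.3 and CU571315.2 had 0 reads in every mutant library and were at least 152-fold and 125-fold lower. Of these, zgc:171490 lies next to si:dkey-19a16.7 in gene order, and zgc:171497 next to fgfr1bl. The 3 si:ch211-153b23 genes that follow irg1l in gene order, si:ch211-153b23.3, si:ch211-153b23.4 and si:ch211-153b23.5, rose with it, by 2.2, 1.57 and 1.52 on the log2 scale.

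Of the 190 genes changed 2-fold or more, 15 have a symbol that belongs to several identifiers, and 7 of these 15 were still called and changed 2-fold when the identifiers were summed. For 1 other chromosome, the share of genes changed 2-fold was higher than elsewhere, at 13 of 553 tested genes (Fisher's exact test, two-sided, odds ratio 3.91, adjusted p = 0.00202 over 25 chromosomes). This test too takes genes that lie together as independent, so its p may be too small. Reads of mitochondrial genes made up 4.21% to 5.85% of each library and those of ribosomal proteins 7.04% to 10.3%.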
